A study of Arabidopsis thaliana with 5 samples.

How the data were processed

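RNA from whole Arabidopsis thaliana plants was measured on 5 one-colour Affymetrix Arabidopsis Genome arrays. Per the labels, plants were at growth stage 1.04 and were grown at 18 degrees and 65% humidity in 16 h light and 8 h dark. Total RNA was extracted with TRIzol and biotin-labelled cRNA was hybridised, per the labels' protocols. The deposited values were intensity values on a linear scale, 1 per probe set and array. From the values, each array had a 2% trimmed mean of about 100, so the authors' table had been brought to a common level before it was deposited. The method that summarised probes into probe sets is not given in the sources used here. No detection calls were used.

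Groups were taken from the accession and line named in the characteristics of each sample, which gave 5 groups of 1 array. These were Col-0 with no line named, the line CAMTA.1.2 in Col-0, the line CAMTA.6.2 in Col-0, WS with no line named, and the line CAMTA.1 in WS. The source names did not follow these characteristics. The Col-0 array with no line named had KO1 in its source name, CAMTA.1.2 had KO2, CAMTA.1 had KO3, CAMTA.6.2 had WSC and WS with no line named had EX1. Arrays are therefore named by what they were labelled, and directions rest on the characteristics.

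The table held 8297 probe sets. The 50 control probe sets were left out, and 8247 were used. A floor was set at the 40th percentile of all values, an intensity of 18.1. Each array was scaled by its median log2 value over the 4245 probe sets above the floor on all arrays, values under the floor were then set to it, and log2 differences were taken. The scaling moved the median log2 difference of CAMTA.1 against WS over these probe sets from 0.00 as deposited to 0.13. A probe set was counted as different at 2-fold or more. Where 1 side was at the floor, the fold is a bound and is given as at least that size. With 1 array per group there was no test of a pairwise difference and no p-value, and the number of arrays limits the precision. The counts of all 10 pairs of arrays are given for comparison. They are not a measure of spread between replicates, since no 2 arrays share a label. No 2 arrays held identical values.

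Gene names came from the platform annotation, updated through gene IDs to the reference gene table of assembly TAIR10.1, which was used for names only. Of the probe sets, 3794 named 1 gene, 70 named several and 4383 named none. No gene was named from a probe set with several. For a gene with several probe sets, the one with the highest mean signal was used. Named genes followed a rule set, with the gene lists, the alternatives and the tests in the design, before the data were examined. The rule took the 10 largest differences in each direction measured on both arrays, the 3 largest bounds in each direction, list members at 2-fold or more, CAMTA family genes, genes called by limma and probe sets shared by the CAMTA.1.2 and CAMTA.1 comparisons. Of 312 loci in 14 lists, 29 had a probe set that named them alone. The others may be among the probe sets without a name. List medians were placed among 10000 random gene lists of the same size matched on mean signal in 20 bins, as a description of these arrays.

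An additive limma model (limma 3.58.1, R 4.3.3) was fitted to 4 arrays, with accession and the lines whose names start with CAMTA.1 as terms. Its 1 residual degree of freedom is the interaction, so its p-values set each effect against that single departure and not against separate plants. The line term takes CAMTA.1.2 and CAMTA.1 as 2 samples of 1 kind, which the labels do not state outright. Adjusted p-values are Benjamini-Hochberg at 0.05. Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation. Overlap between comparisons was set beside that of independent lists and, for the pair sharing the Col-0 array, beside 100 simulations of unchanged arrays. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.

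The steps were tested on simulated data in which 200 probe sets with a mean over 2 times the floor were changed by known folds. Changes nearer the floor were not simulated. For the line term, limma over all 8247 probe sets called 0 of 50 changes at each of 2-fold, 4-fold, 8-fold and 16-fold, because probe sets at the floor on all arrays have no variance. Over the 5681 simulated probe sets above the floor on an array, limma called 8 of 50 changes at 2-fold, 45 of 50 at 4-fold, 50 of 50 at 8-fold and 50 of 50 at 16-fold, with 2 calls among 5481 unchanged probe sets. The 2-fold count, simulated for CAMTA.1.2 against Col-0 over 8247 probe sets, found 24 of 50 changes at 2-fold and 48 of 50 at 4-fold. It also counted 378 of 8047 unchanged probe sets, with a simulated spread that takes the interaction as noise. Of 200 unchanged lists of 6 genes among 2163, 16 fell under the 5th or over the 95th percentile, and all 50 lists moved 2-fold lay over the 95th. The simulated noise was independent between genes, so these shares need not hold for lists whose genes vary together.

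Alternatives were other floors, no scaling, quantile normalization, a pseudocount in place of the floor, a 3-fold threshold, other limma settings and other ways of representing a gene.

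Tests of explanations in the closing section were changed once after results were seen. A first test of root RNA averaged arrays grouped by the values of the root-enriched genes and came out against a larger share of root RNA. It was replaced by tests within labelled comparisons, because arrays should not be grouped by the outcome. These kept its bounds and added a rule that genes 2-fold apart in both directions leave the question open. They leave it open by that rule alone, since their medians and intervals met the bounds against a larger share. A test of the scaling of the arrays as the source of the shared probe sets came out against it and gave way to a test of RNA quality.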

Results

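Expression was measured in whole plants of the Arabidopsis accessions Col-0 and WS and in 3 lines named after CAMTA genes, which encode calmodulin-binding transcription activators. The series title names calcium/calmodulin-binding transcription factors as its subject. Each of the 5 groups had 1 array, so no value below has a replicate. Between 59.0% and 61.9% of the 8247 probe sets lay above the floor on each array. The targeted genes came first as a check of the labels. Probe sets were named for 2 of the 6 CAMTA family genes. CAMTA4 (AT1G67310) was at the floor on all 5 arrays, and CAMTA5 (AT4G16150) had intensities of 15.5 to 21.7, close to the floor of 18.1. The other CAMTA genes were not analysed here, so the labels of the lines could not be checked on a targeted gene.

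The CAMTA.1.2 line was compared with Col-0 to see which transcripts differ in this line. On the array labelled CAMTA.1.2, the thionin gene THI2.1, which encodes an antimicrobial peptide, was at least 11.5-fold lower, from an intensity of 209 on the Col-0 array, although its 3 probe sets ranged in log2 difference from -3.53 to -0.43. WRKY53, a transcription factor of senescence and defence, was at least 3.53-fold lower, and the peroxidase gene AT5G19890 was at 72.5 on the Col-0 array and at the floor on the CAMTA.1.2 array. AT2G41090, which encodes a calmodulin-like protein, was 4.28-fold lower, with 132 against 566. EXO, a gene of brassinosteroid-dependent cell expansion, was 3.86-fold lower, and GH3.3, an auxin-conjugating enzyme gene, at least 3.42-fold lower.

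Further genes lower on the CAMTA.1.2 array were AT2G20870 at 3.71-fold, AT2G18370 at 3.37-fold, the peroxidase gene AT5G39580 at 2.91-fold, AT4G03020 at 2.85-fold, AT2G04570 at 2.81-fold, AT2G32210 at 2.79-fold, the tetraspanin gene TET8 at 2.72-fold and IQD22 at 2.68-fold. Higher genes were fewer. HIS1-3, a drought-inducible linker histone, was 3.25-fold higher, with 269 against 82.7, and AT5G46900, of the lipid transfer protein family, was 3.17-fold higher. AT4G07820 was 2.50-fold higher on the probe set used. Its 4 probe sets ranged in log2 difference from 0, at the floor, to 1.32, with a mean of 0.33. AT2G30600 was 2.42-fold, AT4G32340 2.15-fold and AT1G62510 2.11-fold higher. AT2G21640 was at least 2.35-fold and UGT73C1 at least 2.25-fold higher.

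In all, 33 probe sets were at least 2-fold higher and 126 lower on the CAMTA.1.2 array. This total of 159 was the lowest of the 10 pairs of arrays, which ranged up to 765. With 1 array per group the total does not separate changes from the spread between arrays. Of the lists, the 5 cold and ABA genes had a median log2 difference of -0.35, at the 1.77 percentile of random lists, with no member 2-fold apart. The 6 photosynthesis genes had a median of 0.16 and the 4 auxin genes of -0.22, with GH3.3 alone 2-fold lower and IAA20 and IAA18 higher by 0.80 and 0.27. The Col-0 array was 2-fold above all other arrays at 24 probe sets, THI2.1 among them, so part of what is lower here may lie in that control array.

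**Figure D1:**
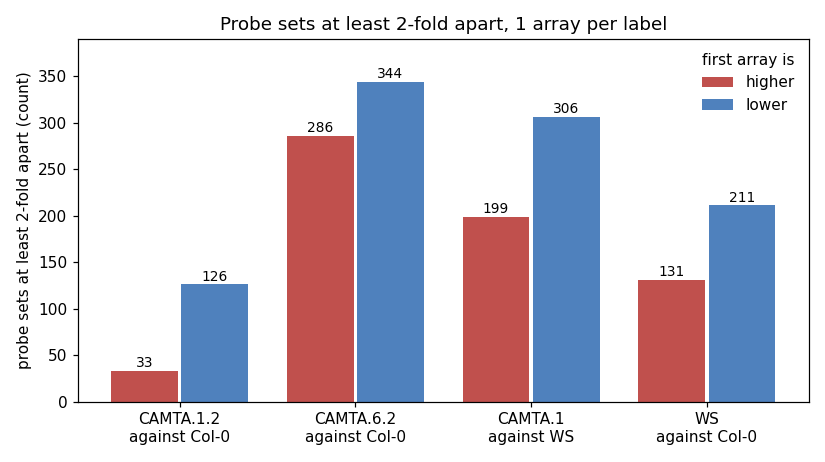
Number of probe sets at least 2-fold higher or lower on the first array of each comparison, from 1 array per label. The bars run from 33 higher and 126 lower for CAMTA.1.2 against Col-0 to 286 higher and 344 lower for CAMTA.6.2 against Col-0.

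The CAMTA.6.2 line, labelled as a segregating insertion line, was compared with the same Col-0 array. Of the 5 cold and ABA genes, 2 were at least 2-fold higher and 1 lower on the array labelled CAMTA.6.2. COR15B, a chloroplast protein gene of cold acclimation, was 4.32-fold higher, with 392 against 90.7, and COR47, a dehydrin gene, was 2.24-fold higher. STZ, a zinc finger repressor of stress responses also called ZAT10, was 3.28-fold lower. The median of the 5 cold and ABA genes was 0.96, at the 99.85 percentile of random lists. LHB1B2, a light-harvesting protein of photosystem II, was 5.11-fold higher, with 2502 against 489, and PSAE-1, a photosystem I subunit, 2.02-fold higher. PSAE-1 fell short of 2-fold with quantile normalization, at a log2 difference of 0.70. PRK and RCA, of carbon fixation, differed by -0.65 and -0.14. The 6 photosynthesis genes had a median of 0.79, at the 99.76 percentile, and of 0.50 with quantile normalization. LHCB4.3, outside the list, was 6.97-fold lower.

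The clock gene GI was 3.20-fold higher on the CAMTA.6.2 array, with 353 against 110. Its 4 probe sets ranged in log2 difference from 0, at the floor, to 2.48. The 3 root-enriched peroxidase genes were also higher, with a median of at least 1.03, at the 99.45 percentile. They were AT3G01190 at 2.93-fold, AT4G26010 at no less than 2.05-fold and AT5G17820 at 1.93-fold, and the first 2 were close to or at the floor on the Col-0 array. The heat shock protein 70 genes Hsp70-2 and AT3G09440 were 3.01-fold and 2.27-fold lower.

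Other genes higher on the CAMTA.6.2 array were AT4G12545, of the lipid transfer protein family, at 11.6-fold, AT2G30600 at 7.42-fold, AT1G62510 at 7.34-fold, AT2G20670 at 6.68-fold, MCCA, of leucine breakdown, at 5.81-fold and AT1G54740 at 5.00-fold. The thionin gene THI2.2 was at least 4.14-fold higher. AT2G20870 was 37.5-fold lower, from 681 to a value barely above the floor, so the size is uncertain. ATA20 was 8.05-fold lower, IAGLU, an indole-3-acetate glucosyltransferase gene, 7.81-fold, the subtilase gene AT4G21650 5.28-fold, AT3G21670 (NPF6.4) 4.99-fold, UGT87A2 4.48-fold and AT1G65500 4.23-fold, with ATA20 and AT3G21670 close to the floor. THI2.1 was at least 11.5-fold lower on the probe set used, but its 3 probe sets ranged in log2 difference from -3.53 to 0.85. The chitinase gene CHI was at least 6.61-fold, the sucrose-phosphate synthase gene ATSPS4F at least 5.59-fold and WRKY53 at least 3.53-fold lower.

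At 2-fold, 286 probe sets were higher and 344 lower, a total of 630. The 3'/5' ratio of the ubiquitin control was 3.57 on this array against 2.64 on the Col-0 array, and that of GAPDH was 1.78 against 1.64.

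The CAMTA.1 line in WS was compared with the WS array. STZ was 5.23-fold lower on the array labelled CAMTA.1, with 68.8 against 360, AT4G27280, which encodes an EF-hand calcium-binding protein, 6.55-fold, and AT4G33720, of the PR-1-like family, 8.34-fold. AT4G33720 was at 400 on the WS array, at 48.0 on the CAMTA.1 array and at no more than 27.1 on the others. The WS array was 2-fold above all other arrays at 14 probe sets, AT4G33720 among them, and below at 12. Part of what differs here may therefore lie in that control array. Hsp70-2 was 3.90-fold and AT3G09440 2.28-fold lower, although AT3G09440 averaged -0.80 in log2 over all its probe sets. THI2.1 was at least 4.61-fold lower on the probe set used, its 3 probe sets ranging from -2.20 to 0.24, and WRKY53 was at least 2.38-fold lower. AT2G20870 was at least 20.2-fold, AT1G09500 at least 11.1-fold and AT3G21670 at least 7.95-fold lower. AT4G21650 was 8.48-fold, AT2G44290 4.60-fold, AT1G05340 4.58-fold, AT2G39850 4.51-fold, AT1G14200 4.22-fold, LHCB4.3 4.12-fold and AT4G17840 4.06-fold lower.

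LHB1B2 was 4.89-fold higher on the CAMTA.1 array, with 1946 against 398, and the 6 photosynthesis genes had a median of 0.66, at the 97.43 percentile. With quantile normalization this median was 0.20. AT4G12545 was 6.29-fold higher, the chitinase family gene AT2G43620 5.68-fold, AT4G11190 5.00-fold, AT1G04040 3.94-fold, AT4G33560 3.80-fold, AT1G62510 3.65-fold, AT4G23820 3.41-fold and AT4G29020 3.36-fold. The peroxidase gene AT2G38390 was at 396 against 94.2. COR15B, at 59.0 against 63.7, and GI, at 160 against 122, were less than 2-fold apart, and the median of the cold and ABA genes was 0.08, or -0.11 with quantile normalization. The root-enriched genes had a median of 0.13.

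At 2-fold, 199 probe sets were higher and 306 lower, which is 39.4% higher of 505. With the values as deposited the split was 131 and 377, or 25.8% higher. The ubiquitin 3'/5' ratio was 3.32 on the CAMTA.1 array against 2.28 on the WS array, while that of GAPDH was 1.29 against 1.38.

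The comparisons of the lines overlapped. CAMTA.1.2 against Col-0 and CAMTA.1 against WS have no array in common and shared 42 probe sets in the same direction, 3 higher and 39 lower. Independent lists would share 5.47, which is too low, since it counts probe sets at the floor on every array of both comparisons. Sharing in opposite directions was also above its value for independent lists, at 11 against 4.26. Named genes lower in both included THI2.1, AT5G19890, AT2G20870, AT2G41090, WRKY53, ATA20, SRC2, TET8, AT2G24550, AT1G30700, AT2G04570 and CHI. SRC2, a C2-domain protein gene, was 2.18-fold lower in the first and 2.77-fold in the second. AT1G12020 and AT1G62510 were higher in both. CAMTA.1.2 and CAMTA.6.2, which were set against the same Col-0 array, shared 64 probe sets, 4 higher and 60 lower. Independent lists would share 6.40, too low for the same reason, and simulated unchanged arrays shared 39 (26 to 49.5). The simulated sharing was 12 higher and 26 lower, so only the sharing of lower probe sets was above it. The 24 probe sets at which the Col-0 array was 2-fold above all other arrays are lower in both by construction. The simulated spread is the same upward and downward, so this excess cannot be told apart from a departure of that control array. The spread of the simulated arrays was taken from the arrays labelled Col-0 and holds any real change among them. With it 881 probe sets were 2-fold apart for CAMTA.6.2, more than the 630 counted, so the simulation matches the data only roughly.

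CAMTA.1 against WS and CAMTA.6.2 against Col-0 also have no array in common, and this overlap was counted after the data were seen. They shared 231 probe sets, 59 higher and 172 lower, and 8 went opposite ways. Independent lists would share 19.7, which is again too low, since it counts probe sets at the floor on every array of both comparisons. Genes higher in both included AT4G12545, LHB1B2, AT2G38390, SKU5, a gene of directional root growth, and PORB, an enzyme gene of chlorophyll synthesis. PORB was 2.30-fold higher in the first and 3.90-fold in the second. Genes lower in both included AT2G20870, LHCB4.3, STZ, Hsp70-2 and ATSPS4F. Without these 231 probe sets, 274 remained 2-fold apart for CAMTA.1 and 399 for CAMTA.6.2. The ubiquitin 3'/5' ratio was higher on both of these line arrays than on their control arrays.

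**Figure D2:**
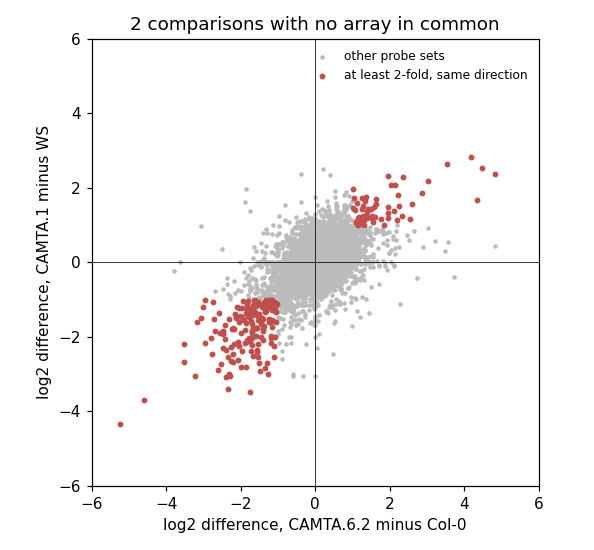
Log2 difference of each probe set in CAMTA.6.2 minus Col-0 (horizontal axis) and CAMTA.1 minus WS (vertical axis). The 231 probe sets at least 2-fold apart in the same direction in both, 59 higher and 172 lower, are in red and all others in grey.

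WS was compared with Col-0 on the arrays that name no line. ECS1, a gene known to differ between accessions, was 70.2-fold lower on the WS array, with 97.3 against 6832. The drought-induced gene DI21 was 5.80-fold lower, AT1G76960 12.7-fold, AT5G44286 12.5-fold, AT2G33220 10.9-fold, AT1G23130 6.09-fold, AT2G31490 5.16-fold, CP5 4.71-fold and the chitinase family gene AT2G43590 4.56-fold. The 2 probe sets of AT5G44286 ranged in log2 difference from -3.64 to 0, so its size holds for the probe set used only. AT4G02540 was at least 6.75-fold and AT1G65190 at least 4.69-fold lower. AT4G33720 was 14.8-fold higher, AT2G35820 8.02-fold, the jacalin lectin gene AT1G52050 4.85-fold, AT1G02300 4.54-fold, AT5G55070 4.19-fold, AT4G12545 4.17-fold, AT5G46900 3.77-fold and the peroxidase gene AT4G11290 3.14-fold. AT1G78860 was at least 7.27-fold higher. The CAMTA.1 array, also labelled WS, did not share all of these, since AT4G33720 was at 48.0 there against 400 on the WS array and AT2G43590 at 346 against 118. AT5G46900 was also higher than on the Col-0 array on the CAMTA.1.2 and CAMTA.6.2 arrays, at 148 and 198.

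The 3 root-enriched peroxidase genes had a median of at least 1.26 in WS against Col-0, at the 100 percentile, and AT3G01190 was 5.49-fold higher. That median is the value of AT4G26010, which was under the floor on the Col-0 array. The cold and ABA genes had a median of -0.51, at the 1.44 percentile, with the dehydrin gene LTI30 3.37-fold and KIN2 2.37-fold lower. The photosynthesis genes had a median of -0.30, or -0.056 with quantile normalization, and the auxin genes of 0.01, although GH3.3 was at least 3.42-fold lower. At 2-fold, 131 probe sets were higher and 211 lower, which is 38.3% higher of 342, or 48.7% with the values as deposited.

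All splits of the 5 arrays into 2 and 3 were counted as a check of the accession labels. The labelled split of WS and CAMTA.1 from the others had 65 probe sets 2-fold apart and 9 at 8-fold. The split of CAMTA.6.2 and CAMTA.1 from the others had 116 at 2-fold and 1 at 8-fold, and no other split had more than 27 at 2-fold or 1 at 8-fold. ECS1 was at 6832, 4865 and 3545 on the arrays labelled Col-0 and at 97.3 and 39.1 on those labelled WS. AT2G33220 was at 275, 287 and 316 against 25.2 and 3.80, and AT1G02300 at 27.4, 30.9 and 31.3 against 124 and 195.

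**Figure D3:**
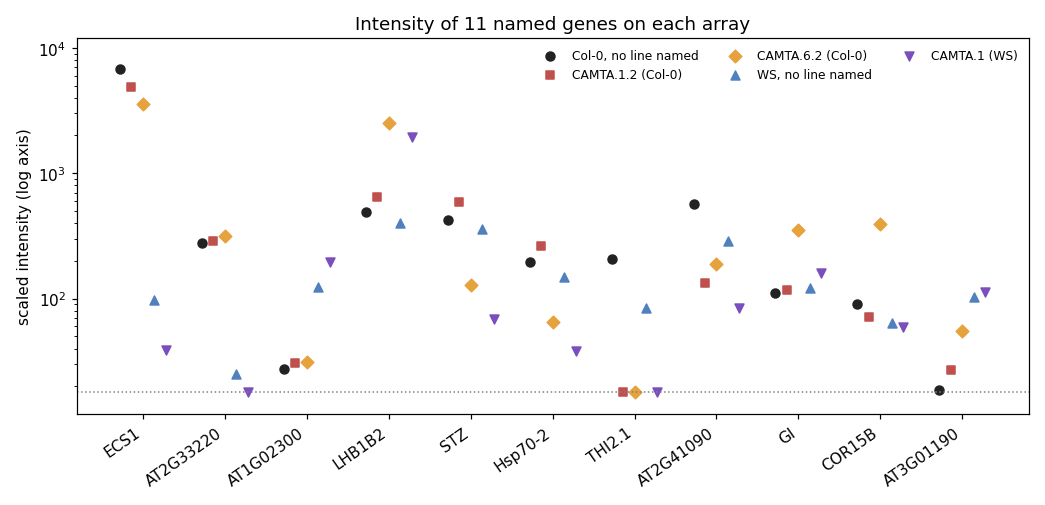
Scaled intensity of 11 named genes on the 5 arrays, on a log axis, with 1 point per array and the floor of 18.1 as a dotted line. Points at the line are at or under the floor. ECS1 lies between 3545 and 6832 on the arrays labelled Col-0 and at 97.3 and 39.1 on those labelled WS.

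In the additive limma model over all 8247 probe sets, no probe set passed for the line or for the accession, with 484 and 655 at an unadjusted p under 0.05. On data simulated with line effects this fit called none of the changes, so its count of 0 for the line carries no information. Accession effects were not simulated, but the accession term has the same residual and prior degrees of freedom, 1 and 0.351. Its count of 0 can therefore not be read as an absence of differences. Restricted to the 5540 probe sets above the floor on an array, limma called 0 for the line, with 307 unadjusted, and 59 for the accession, 13 higher and 46 lower in WS. Of these, 6 of the higher and 20 of the lower named 1 gene. The 0 for the line bears only on an effect common to CAMTA.1.2 and CAMTA.1, which the model takes as 1 kind. CAMTA.1 shared 42 probe sets with CAMTA.1.2 and 231 with CAMTA.6.2, so that assumption is doubtful. The CAMTA.6.2 array, labelled Col-0, was not in this fit. It lay with the other Col-0 labels for ECS1 but not for every call, so not all calls follow accession. ATA20, called lower, was at 163 on the Col-0, 67.7 on the CAMTA.1.2, 50.9 on the WS and 22.3 on the CAMTA.1 array. On the CAMTA.6.2 array it was at 20.2. An unnamed probe set called higher was at 30.9, 36.2, 286 and 1493 in that order, and at 874 on the CAMTA.6.2 array. ECS1 had a log2 difference of -6.55 (SE 0.304, adjusted p = 0.00065 by limma) and AT3G01190 of 2.26 (SE 0.269, adjusted p = 0.017). AT2G33220 had one of -3.72 (SE 0.279, adjusted p = 0.0031) and AT1G78860 one of 3.19 (SE 0.288, adjusted p = 0.0071). The sizes for AT2G33220 and AT1G78860 are bounds. AT2G33220 was under the floor on the CAMTA.1 array, and AT1G78860 on the Col-0 and CAMTA.1.2 arrays. The drought-induced genes DI21 and DI19 fell by 2.23 and 2.18.

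The limma fit over all probe sets called 0 genes in every list, adjusted over the list alone or over all genes. For the line this carries no information either, and for the accession it cannot be read as absence. Of the list members, AT3G01190 of the root-enriched genes was called for the accession over the probe sets above the floor. With camera the root-enriched genes were higher in WS (adjusted p = 0.024), but not with an estimated correlation (adjusted p = 0.70). The photosynthesis genes did not pass for the line (adjusted p = 0.13 with the preset correlation and 0.90 with the estimated one). Camera used the fit over all 8247 probe sets, of which 2707 were at the floor on all 4 arrays and could not differ. The estimated correlations rest on 1 residual degree of freedom. The camera results therefore settle neither list. No probe set was named for the lists of calcium signalling, flower and seed, and cell cycle genes. The named probe sets of the phenylpropanoid and accession-variable genes were at the floor on all arrays.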

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

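HIS1-3 and AT2G21640 differed at least 2-fold in opposite directions in the lines CAMTA.1.2 and CAMTA.1, and this difference between the lines was not tested, since each has 1 array. HIS1-3 had a log2 difference of 1.70 in CAMTA.1.2 against Col-0 and of -1.11 in CAMTA.1 against WS. AT2G21640, a gene raised by oxidative stress, had differences of 1.23 and -1.58, the first of them a bound. Among all probe sets, 11 went opposite ways at 2-fold in these comparisons. Independent lists would give 4.26, a value that is too low because it counts probe sets at the floor.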

How the results depend on the processing

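Gene and list results were rerun with the values as deposited, with quantile normalization, with the mean over all probe sets of a gene and with unfloored medians. They were not rerun with other floors or a pseudocount. The scaling factors ran only from -0.046 to 0.089 in log2, so leaving them out could not turn a 2-fold difference. No named gene at 2-fold turned direction in these runs. Values near 0 did: the cold and ABA median in CAMTA.1 against WS went from 0.08 to -0.11 with quantile normalization, and CAMTA5 from 0.07 to -0.06 as deposited. With each gene and list result counted once per rerun, 411 were labelled the same, 9 came under 2-fold and 2 came to it. No paired analysis was possible because no replicate numbers pair samples across groups, and the limma model sets the line effect within each accession instead. The floor and the threshold both moved the counts. In the order CAMTA.1.2 against Col-0, CAMTA.6.2 against Col-0, CAMTA.1 against WS and WS against Col-0, the 2-fold totals of 159, 630, 505 and 342 became 506, 1089, 909 and 758 with the floor at the 20th percentile, and 86, 397, 320 and 208 at the 60th. At 3-fold they were 32, 217, 155 and 116 by construction. A pseudocount gave 90 for CAMTA.1.2. In 2 settings chosen after seeing the data, the totals moved by construction. With only probe sets without a suffix letter, the totals were 403 for CAMTA.6.2, 305 for CAMTA.1 and 223 for WS, and without the probe sets shared by CAMTA.1 and CAMTA.6.2 they were 399 for CAMTA.6.2 and 274 for CAMTA.1. The overlap of CAMTA.1.2 and CAMTA.1 was 91 and 27 with the lower and higher floor, 24 with the pseudocount and 13 at 3-fold, that of CAMTA.1.2 and CAMTA.6.2 was 197, 39, 41 and 15, and that of CAMTA.1 and CAMTA.6.2, itself added after seeing the data, was 152 with the higher floor and 73 at 3-fold. Probe sets separating the accession labels numbered 104 with the lower floor and 33 at 3-fold. With the CAMTA.6.2 array included and coded as having no such line, the limma line term over all probe sets called 1, AT1G12020. That call rests on 3 arrays set to the floor, which leaves an SE of 0.0031. The accession term called 59 over probe sets above the floor, where those without variance are left out. For the floor, the pseudocount and the added array the cause was not tested. Signal near the floor of 18.1 limits all bounds.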

Other observations

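The CAMTA.6.2 array stood apart from all other arrays more often than any other single array, with 67 probe sets at least 2-fold above and 27 below the other 4. The genes named here were chosen after their values were seen. The vacuolar sugar transporter gene SWEET17 was at 58.6 against 17.9 to 23.2 elsewhere, and the methionine sulfoxide reductase gene MSRB6 at 45.8 while it was under the floor on the other arrays. The glycosyltransferase gene UGT84A3 was at 60.8 against 144 to 240, UGT87A2 at 37.8 against 141 to 273 and IAGLU at 34.1 against 121 to 405, while UGT85A2, of the same family, was highest on this array at 318. The expansin gene EXPA8 was at 77.7 against 164 to 284.

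On the CAMTA.1 array, 16 probe sets were 2-fold above and 31 below all others. FIB, a plastoglobule protein gene, was at 66.7 against 201 to 311, and the methionine sulfoxide reductase gene MSRB9 at 54.5 against 20.6 to 23.1. The 5S rRNA control was at 276 on this array against 59.4 to 101.

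All tests in the paragraphs that follow were chosen after the results they bear on were seen. Of the probe sets shared by CAMTA.1 against WS and CAMTA.6.2 against Col-0, 29 of 231 were 2-fold apart the same way in CAMTA.1.2 against Col-0, and their median signed log2 difference there was 0.11 (95% interval over probe sets -0.0088 to 0.23), against medians of 1.53 and 1.64 in the comparisons that define them. This argues against an effect common to all 3 arrays labelled with a CAMTA line, for the set as a whole. It does not for part of the set, since 12.6% is above the 1.93% of all probe sets 2-fold apart in CAMTA.1.2. However, the 1.93% counts probe sets at the floor, which could not differ. The Col-0 array that 2 of the comparisons share would also favour such sharing. Lower RNA quality may contribute and cannot be told apart, because the ubiquitin 3'/5' ratio was 1.46 and 1.35 times that of the control arrays for CAMTA.1 and CAMTA.6.2 but the GAPDH ratio was 0.93 and 1.08 times. A different time of day at harvest also stays open. GI, the 1 clock gene of the list with a named probe set, had a log2 difference of 0.40 in CAMTA.1 against WS and of 1.68 in CAMTA.6.2 against Col-0. An effect of these lines alone was not tested.

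The root-enriched genes were higher on the WS and CAMTA.6.2 arrays than on the Col-0 array, and a larger share of root RNA is a candidate explanation. It was tested on other class III peroxidase genes, a mostly root-expressed family. Their median log2 difference was -0.029 (95% interval over genes -0.29 to 0.28) over 33 genes in WS against Col-0 and 0.20 (-0.048 to 0.45) over 31 genes in CAMTA.6.2 against Col-0. Of these genes, 3 and 2 were 2-fold higher and lower in the first and 6 and 5 in the second, so members went both ways. By a rule added with these tests, this leaves the share of root RNA open. On the medians and intervals alone, both tests would have come out against a larger share. Accession cannot by the labels make the CAMTA.6.2 and Col-0 arrays differ, and the lowest difference of the root-enriched genes between them was 0.95, but the test reached no result because only 1 of the 3 genes had both values over 2 times the floor.

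The array labelled CAMTA.6.2 in Col-0 has WSC in its source name, so it could hold WS RNA. Of the 22 probe sets at least 8-fold apart between the WS and Col-0 arrays, 19 (86.4%) lay nearer the Col-0 level on the CAMTA.6.2 array, as did 20 on the CAMTA.1.2 array, while 18 lay nearer the WS level on the CAMTA.1 array. This argues against WS RNA on the CAMTA.6.2 array, given that the labels of the WS and Col-0 arrays are right. Over the 342 probe sets 2-fold apart the same counts were 207, 260 and 247. Which arrays are the knockout lines that KO1 to KO3 name stays open.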
